A study of Mus musculus with 12 samples.

How the data were processed

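Heart RNA of 12 mice was hybridised to 12 Affymetrix mouse arrays with a single biotin label, per the labels' protocols, 3 mice for each of 4 groups (wake MI, wake sham, sleep MI, sleep sham). The deposited values are an intensity per probe set on a linear scale, 1 column per array, summarised with MAS5 per the submitters' processing notes. The MAS5 version, its settings and the detection calls are not given in the sources used here, and scanner files were not used here. The mean after trimming 2% of probe sets at each end was 150 on each of the 12 arrays, so the values had been brought to a common level. No further scaling was applied. Per the labels' protocols, hearts were snap frozen and total RNA was extracted with Trizol. No batch, slide or scan date is given in the sources used here, so batches were not tested.

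Of 22690 probe sets, 64 controls were left out of the tests. The annotation table of the array gave 1 gene symbol for 20380 of the other 22626 probe sets, several for 691 and none for 1555, and only the first kind was named. Through a mouse gene table (assembly GRCm38.p6, used for names alone), 12370 of the gene identifiers matched and 24 did not, and 0 symbols changed. Each of 12393 genes was represented by its probe set with the highest mean, and 8101 genes were tested whose mean over all 12 arrays reached the 40th percentile of all probe sets, a signal of 16.8. Values were transformed as log2(signal + 16), and fold changes are on that scale, which mostly understates the change of genes with low signals. Signals, given as mean ± SD of 3 arrays, are the deposited values. MAS5 signals near the low end carry little information on order, so small differences there were not read.

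Groups were compared with limma 3.58.1 in R 4.3.3 (statmod 1.5.0), with 1 mean per group over all 12 arrays, an intensity trend in the moderated variances and two-sided tests, which left 8 residual degrees of freedom and 14.0 with the prior. Benjamini-Hochberg adjustment was made over the 8101 genes within each of 6 comparisons, and a gene was called at an adjusted p below 0.05. The comparisons were MI against sham over both times, in wake hearts and in sleep hearts, wake against sleep among MI and among sham hearts, and the difference of the MI effect between wake and sleep. An exact permutation test of 3 against 3 arrays cannot give a two-sided p below 0.1, so single genes were tested with limma alone. Of 32 gene lists, 30 were tested with camera at a preset correlation of 0.01, adjusted over the 30 lists. The lists of T, B and NK lymphocyte markers (2 of 22 genes measured) and of erythroid and blood RNA (3 of 10) were not tested, the minimum being 4. Camera with an estimated correlation called 0, 0, 3, 1, 2 and 0 lists in the 6 comparisons in the order above, against 14, 15, 14, 7, 12 and 8. Figures were drawn with matplotlib 3.10.9 from tables made with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.

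The groups, comparisons, gene lists, tests and most alternatives were fixed before the data were examined, as was the rule for the genes named. It takes, in each comparison, the 8 genes with the largest rise and the 8 with the largest fall among called genes whose groups do not overlap (at both times for the comparison over both times, with no overlap condition for the difference of effects), up to 3 members of each called or discussed list with the smallest adjusted p in its direction, and a panel of 22 genes called or not. Where fewer pass, all are taken, and the tail of the first part may be left out but never replaced. Of the panel, Tnf lay below the level filter and Cpt1b had no probe set with a single symbol. Probe sets of a named gene that differ in direction or call are said to.

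On 1 set of 12 simulated arrays, with the means and spreads of the 8101 genes, the test of wake MI against wake sham recovered 93% of 100 genes changed by log2 1 and 98% of 100 changed by log2 2, with 0 of the wrong sign. It also called 18 unchanged genes, 8.61% of its 209 calls and above the 5% at which genes are called, so the counts of called genes given here may hold more wrong calls than the adjusted p states. In a comparison without changes it called 0 genes. A list of 25 genes shifted by log2 0.5 gave an adjusted p of 6.11e-28, and 0 lists passed in the unshifted comparison. The simulated genes varied independently of each other, so this does not show how often lists of genes that move together pass without a change. Alternatives were pseudocounts of 1 and 64, no level filter or the 60th percentile, quantile normalization, median centring, all probe sets one by one, the mean of a gene's probe sets, variances without a trend or with robust estimation, array weights, the compared groups alone, the replicate number as a block, each array left out, an adjusted p below 0.01, a log2 change of at least 1, camera with an estimated correlation, and fry. The log2 ratio of the 3' to the 5' beta-actin control signal as a covariate, and leaving out the 2 arrays of highest ratio, were added after seeing the data.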

Results

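Messenger RNA was measured in the hearts of 12 C57Bl/6 mice, an inbred laboratory strain, on 12 single-colour Affymetrix arrays, 1 per mouse. The mice formed 4 groups of 3. They had either myocardial infarction (MI), made by tying off the left anterior descending coronary artery, or sham surgery, and the surgery fell in either the wake or the sleep period of the day. Wake surgery took place between ZT13 and ZT15 and sleep surgery between ZT1 and ZT3, where ZT (zeitgeber time) counts hours from lights on. Hearts were collected 8 hours after surgery, at ZT23 in the wake groups and at ZT11 in the sleep groups. Time of surgery and time of collection changed together, so each difference between wake and sleep groups belongs to both. The MI samples are described as infarcted myocardium, and the part of the sham hearts that was taken is not given in the sources used here.

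The median signal of a probe set lay between 32.7 and 34.7 on the 12 arrays, and 6824 to 7006 probe sets had a signal of 100 or more. Correlation across genes, which are not independent replicates, was 0.974 to 0.988 between arrays of the same group (12 pairs) and 0.949 to 0.989 between arrays of different groups (54 pairs). No pair of arrays held identical values. The number of arrays, 3 per group, limits the precision of each value. The ratio of the 3' to the 5' beta-actin control signal, which rises as RNA breaks down, was 1.79 ± 0.02 in wake sham, 2.60 ± 0.62 in wake MI, 2.40 ± 0.45 in sleep MI and 2.18 ± 0.28 in sleep sham hearts (mean ± SD, n = 3 each). The highest value was 3.31, in wake MI replicate 3. Signals of the added hybridisation controls averaged 9.41 ± 0.03 on the log2 scale in wake sham hearts, against 9.81 ± 0.08 in wake MI, 9.68 ± 0.01 in sleep MI and 9.67 ± 0.07 in sleep sham hearts (SD, n = 3 each).

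The first comparison asked which genes differed between MI and sham hearts 8 hours after surgery over both times of day, with 6 arrays a side. The largest rises were those of Hspa1b, Fos, Hspa1a, Ptx3 and Atf3. Fos, a transcription factor gene switched on soon after a stimulus, was 14.5-fold higher after MI (log2 3.86, SE 0.28, adjusted p = 1.45e-06). Its signals were 1100 ± 642 against 46.9 ± 7.97 in wake hearts and 1248 ± 287 against 88.2 ± 54.3 in sleep hearts (SD, n = 3 each). Hspa1b and Hspa1a, near-identical copies of an inducible heat shock protein gene whose probe sets cannot be told apart with certainty, were 29.5-fold (log2 4.88, SE 0.36) and 14.1-fold (log2 3.82, SE 0.24) higher. Il6, which codes for an inflammatory cytokine, rose at least 9.88-fold (log2 3.30, SE 0.36, adjusted p = 4.66e-05), and Ptx3, a secreted pattern recognition protein of acute inflammation, rose at least 12.4-fold (log2 3.63, SE 0.46). Fold changes here are ratios on the log2(signal + 16) scale, which mostly understates the change of genes with low signals. Among these were Il6, Ptx3, Cxcl2, Hdc, Il1r2 and Selp, whose mean signal in wake sham hearts lay below 16. Atf3, a stress-induced transcription factor, rose 11.5-fold (log2 3.52, SE 0.20). The matricellular gene Ccn1 and the immediate early gene Egr1 rose 10.1-fold and 8.98-fold. Among the genes that fell most were Rsrp1 (log2 -1.36, SE 0.22), Cdh11, a cadherin of mesenchymal cells (log2 -1.28, SE 0.18), and Hpgd, which breaks down prostaglandins (log2 -1.19, SE 0.11). For each of these genes every MI array lay on one side of every sham array at both times.

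By limma with Benjamini-Hochberg adjustment over 8101 genes, 1792 genes differed, 688 higher and 1104 lower after MI. Of these, 125 differed at least 2-fold, 119 higher and 6 lower. With the beta-actin ratio as a covariate, chosen after seeing the data, 672 genes differed. The median absolute log2 of all genes was 0.159 without and 0.158 with it, and the median standard error was 1.28 times as large. Of the 60 called genes named by the fixed rule, 47 kept their call in each alternative and with each array left out, and 7 more lost it only with that covariate. With 1 array left out, 4 lost it, Actn2 and Tcap for 6 of the arrays, Ttn for 7 and Col1a1 for 8.

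Of 23 immediate early genes tested, 21 rose and 2 did not pass (median log2 1.18; 21 higher adjusted over the list alone). Btg2, which slows cell division, was among them (log2 2.16, SE 0.11). The list stood above the other genes (camera, adjusted p = 7.53e-26; adjusted p = 0.0768 with an estimated correlation). All 10 neutrophil markers rose (median 1.31; 10 adjusted over the list alone, adjusted p = 7.91e-09, and adjusted p = 0.154 with an estimated correlation). They included the calcium-binding protein gene S100a8 at 2.99-fold (log2 1.58, SE 0.27), the decoy receptor Il1r2 (log2 1.73) and the histamine-forming enzyme Hdc (log2 1.42). Of 20 cytokine and chemokine genes, 12 rose, 2 fell and 6 did not pass (median 0.66; 12 higher and 2 lower adjusted over the list alone, adjusted p = 4.82e-06, and adjusted p = 0.206 with an estimated correlation). The neutrophil-attracting chemokine Cxcl1 rose 5.63-fold (log2 2.49, SE 0.37), Cxcl2 by log2 2.16 and the monocyte-attracting Ccl2 by log2 1.29 (SE 0.23). Among 14 monocyte and inflammatory macrophage markers 4 rose, 2 fell and 8 did not pass (median 0.16; 5 higher and 2 lower adjusted over the list alone, adjusted p = 0.0471, and adjusted p = 0.478 with an estimated correlation). This call ended without wake MI replicate 2, wake sham replicate 1 or 2, sleep MI replicate 3 or sleep sham replicate 3 (adjusted p = 0.0713 to 0.115), and the median was 0.29 without wake sham replicate 3. It ended with the beta-actin covariate too (median 0.09, adjusted p = 0.125). Leukocyte adhesion genes gave 6 of 14 higher and none lower (median 0.23; 6 adjusted over the list alone, adjusted p = 0.00172, and adjusted p = 0.170 with an estimated correlation). Selp, the P-selectin gene, stood at log2 1.76. Pattern recognition and inflammasome genes gave 6 higher, 1 lower and 7 not passing (median 0.24; 7 higher and 1 lower adjusted over the list alone, adjusted p = 0.00617, and adjusted p = 0.154 with an estimated correlation). With the beta-actin covariate their median was 0.13 (adjusted p = 0.0464).

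Wound matrix and proteolysis genes gave 12 of 21 higher, none lower and 9 not passing (median 0.75; 14 higher adjusted over the list alone, adjusted p = 2.82e-12, and adjusted p = 0.0768 with an estimated correlation). The secreted protease Adamts1 stood at log2 2.27 (SE 0.14) and the lipid kinase Sphk1 at log2 2.57. Of 14 fetal and stress genes of the cardiomyocyte 10 rose and 4 did not pass (median 1.12; 10 higher and 1 lower adjusted over the list alone, adjusted p = 6.71e-10, and adjusted p = 0.114 with an estimated correlation). They included Hbegf, a growth factor (log2 2.60), the muscle repair gene Xirp1 (log2 2.04) and the natriuretic peptide gene Nppb at 5.72-fold (log2 2.52, SE 0.46, adjusted p = 0.00199). The other natriuretic peptide gene, Nppa, did not pass (log2 -0.75, SE 0.32, adjusted p = 0.102). Glucocorticoid-responsive genes gave 12 of 19 higher, 1 lower and 6 not passing (median 0.89; 13 higher and 1 lower adjusted over the list alone, adjusted p = 6.71e-10, and adjusted p = 0.170 with an estimated correlation). Among these genes the metallothionein gene Mt2 rose 4.83-fold (log2 2.27, SE 0.23) and the cell-cycle inhibitor Cdkn1a by log2 1.75. In the hypoxia and glycolysis list 9 of 23 rose, none fell and 14 did not pass (median 0.25; 12 higher adjusted over the list alone, adjusted p = 6.60e-07, and adjusted p = 0.151 with an estimated correlation). Members that rose were Hif1a, the hypoxia-inducible transcription factor (log2 1.03), and the glycolysis regulator Pfkfb3 (log2 1.20). Heat shock and unfolded protein genes gave 11 of 25 higher, 1 lower and 13 not passing (median 0.18; 11 higher and 1 lower adjusted over the list alone, adjusted p = 7.03e-05, and adjusted p = 0.154 with an estimated correlation).

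Endothelial markers gave 9 of 21 higher, 4 lower and 8 not passing (median 0.16; 9 higher and 5 lower adjusted over the list alone, adjusted p = 0.0367, and adjusted p = 0.478 with an estimated correlation). Antioxidant and metallothionein genes gave 6 of 16 higher, 2 lower and 8 not passing (6 higher and 2 lower adjusted over the list alone, adjusted p = 0.0367, and adjusted p = 0.478 with an estimated correlation). Their mean of 0.29 and median of -0.03 differ in sign. Cardiomyocyte contractile genes gave 3 of 26 higher and 23 not passing (median 0.10; 0 adjusted over the list alone, adjusted p = 0.00172, and adjusted p = 0.478 with an estimated correlation). These 3 were the sarcomere genes Actn2 (log2 0.22), Tcap (log2 0.20) and Ttn (log2 0.22). The endothelial call ended without wake MI replicate 3 or sleep MI replicate 1 (adjusted p = 0.178 and 0.0502), and the antioxidant call without wake MI replicate 1 or 2, wake sham replicate 3 or sleep MI replicate 2 (adjusted p = 0.0504 to 0.131). Without single arrays the antioxidant median ran from -0.04 to 0.07, and the contractile median was 0.05 without sleep sham replicate 2. With the beta-actin covariate the endothelial call ended (median 0.03, adjusted p = 0.484). The antioxidant and contractile calls held with it, at medians of 0.10 and 0.07 (adjusted p = 0.00420 and 0.0153). In the other 16 lists the camera test did not pass. Oxidative phosphorylation had 0 of 39 genes called (0 adjusted over the list alone; median 0.03, adjusted p = 0.0810). Fatty acid oxidation gave 4 higher and 1 lower of 28, with adjusted p = 0.206 and a median of -0.01 against a mean of 0.08. Fibroblast and collagen genes gave 0 higher and 4 lower of 21 (median -0.12, adjusted p = 0.174). The atrial markers gave 0 higher and 1 lower of 7 (median -0.75, adjusted p = 0.0810). Adipose markers gave 2 higher of 6 (adjusted p = 0.0810) and smooth muscle and pericyte markers 2 higher and 2 lower of 13 (adjusted p = 0.221). Resident macrophage markers gave 1 lower of 15 (median -0.25, adjusted p = 0.174) and ion channels 2 lower of 15 (adjusted p = 0.660). Cell cycle genes gave 1 higher of 14 (adjusted p = 0.166), mesothelial markers 1 higher of 4 (adjusted p = 0.235) and skeletal muscle markers 0 of 4 (adjusted p = 0.979). The cell death list gave 3 higher and 3 lower of 16 (adjusted p = 0.162; median -0.01, mean 0.10) and the complement and coagulation list 3 higher and 4 lower of 13 (adjusted p = 0.931; median -0.21, mean 0.09). The interferon-stimulated list gave 1 lower of 20 (adjusted p = 0.569; median -0.01, mean -0.02, with a positive test direction).

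Of the panel fixed for every comparison, Il1b (log2 0.83), the calprotectin gene S100a9 (log2 1.68), the protease inhibitor Timp1 (log2 1.18), Pdk4, which holds back glucose oxidation (log2 0.82), and Ppargc1a, a regulator of mitochondrial genes (log2 1.12), rose over both times. The clock gene Per3 (log2 -0.73, SE 0.17, adjusted p = 0.00755) and the collagen gene Col1a1 (log2 -0.48, SE 0.15, adjusted p = 0.0376) fell, Col1a1 in 1 of its 2 probe sets. Arntl, Dbp, Nr1d1, Per2, Myh6, Myh7 and Atp2a2 did not pass (log2 -0.04, -0.22, 0.44, 0.02, 0.15, -0.44 and 0.12). However, 1 of 2 probe sets of Myh6 and 1 of 4 of Atp2a2 had the opposite sign. The clock genes of the Bmal1 and Clock arm gave 1 higher of 6 (adjusted p = 0.129). Per, Rev-erb and PAR bZIP clock genes gave 2 higher and 3 lower of 11 (adjusted p = 0.621; median -0.12, mean 0.03).

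**Figure D1:**
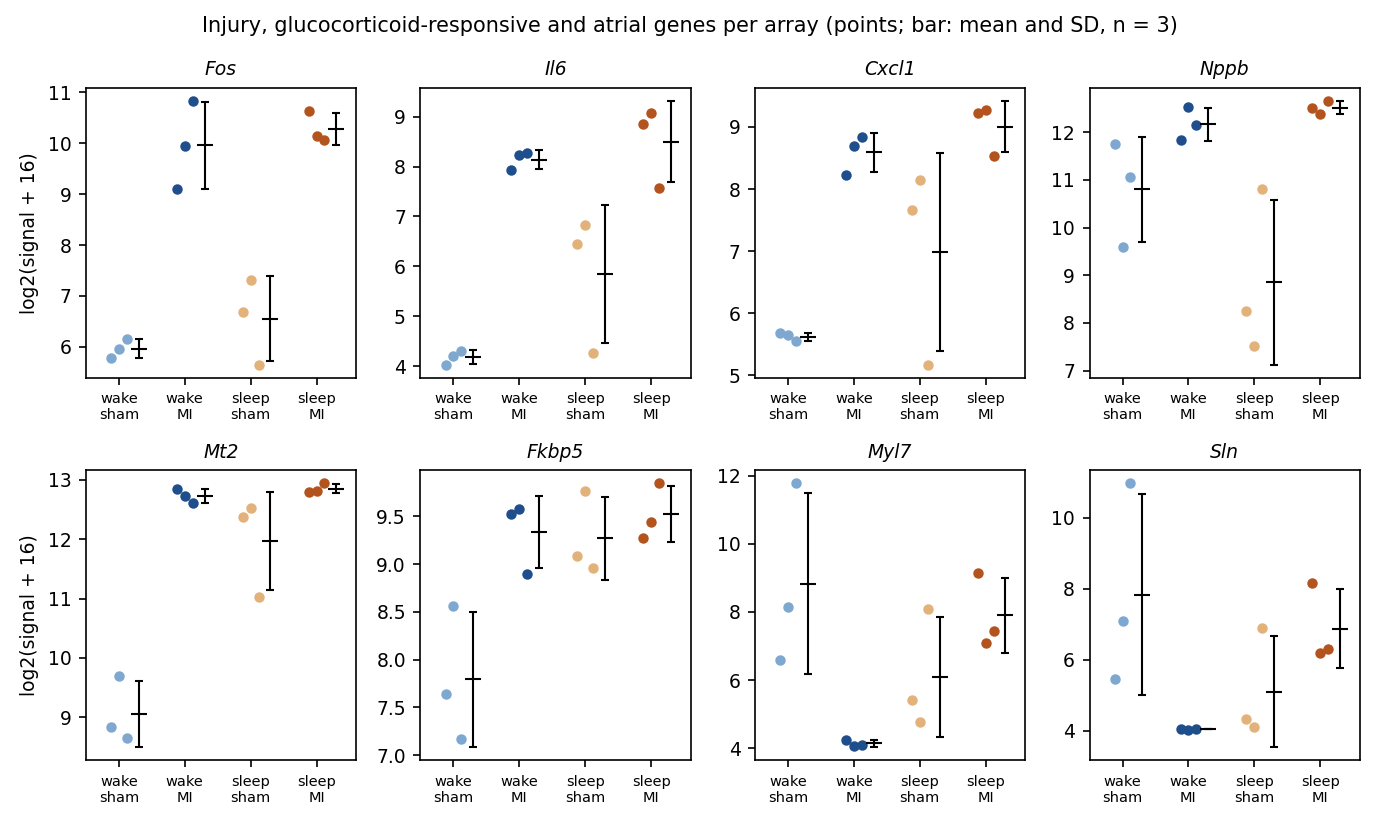
Signals of 8 genes on each of the 12 arrays, as log2(signal + 16), by group (points are arrays, bars mean and SD, n = 3). Fos and Il6 were higher in MI than in sham hearts at both times, while Mt2 reached 4402 in sleep sham hearts and 547 in wake sham hearts. Fkbp5, a glucocorticoid-responsive gene, was chosen after its values were seen.

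The next comparison set wake MI against wake sham hearts, 3 arrays each. On the log2(signal + 16) scale Ptx3, Hspa1b, Fos and Il6 rose most, and the 3 largest falls were in genes typical of atrial muscle. Ptx3 was at least 23.4-fold higher (log2 4.55, SE 0.65, adjusted p = 0.000570). Il6 was at least 15.5-fold higher (log2 3.96, SE 0.51, from a signal of 2.23 ± 1.70 to 268 ± 35.6, SD, n = 3 each) and Mt2, which binds metals, was 12.7-fold higher (log2 3.67, SE 0.32, from 547 ± 233 to 6792 ± 540, SD, n = 3 each). Hspa1b rose 17.7-fold, Fos 15.9-fold (log2 3.99, SE 0.40), Egr1 14.1-fold and Socs3, a feedback inhibitor of cytokine signalling, 11.3-fold. Myl7 and Myl4, which code for atrial myosin light chains, fell by 4.69 (SE 1.05) and 3.14 (SE 0.80) on the log2 scale, and Sln, an atrial inhibitor of the calcium pump, by 3.80 (SE 1.06). Sham signals of these 3 genes varied widely, with Myl7 at 1274 ± 1909 in wake sham against 1.67 ± 1.24 in wake MI hearts (SD, n = 3 each). Mean signals of Il6 and Ptx3 in wake sham and of Myl7 and Sln in wake MI hearts lay below the 16 added before the log, so that constant sets the sizes and ranks of these changes. With 1 added they were 6.54, 5.72, -7.40 and -7.08, and with 64 added 2.32, 3.18, -3.07 and -2.34. Inmt, a methyltransferase (log2 -1.62), Cdh11 (log2 -1.62) and the endothelial transcription factor gene Sox18 (log2 -1.33) fell as well. Aplnr (log2 -1.94) and Fmod (log2 -1.35) fell in 1 of their 2 probe sets each. Fmod had a mean signal of 6.28 in wake MI hearts, and its change was -0.87 with 1 added and -0.60 with 64 added.

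In limma 1496 genes differed, 631 higher and 865 lower, and 228 of them by at least 2-fold. With median centring 675 were called higher and 712 lower. The groups did not overlap in 1456 of the 1496, and in 35.1% of all genes tested against 10% by chance. The count was 863 without wake sham replicate 1, 845 without wake sham replicate 3. It was 274 with the beta-actin ratio as a covariate, but that ratio separated the wake groups, so it cannot test RNA integrity. That covariate ended the calls of 29 of the 59 called genes named by the fixed rule, among them Myl7, Sln, Myl4, Egr1, Socs3, Cxcl1, S100a8, Inmt, Sox18, Aplnr, Fmod and Col1a1. With it all 29 kept their sign and 25 had a smaller change, the ratio of log2 with to without being 0.840 in the median (0.457 to 1.30), and the standard error was 1.43 times as large in the median. Of the 59, 12 lost the call with 1 array left out. These were Fmod and Tcf21 (wake sham replicate 3), Inmt (wake MI replicate 2), Sele (wake sham replicate 2), Sln (wake MI replicate 1, 2 or 3 or wake sham replicate 3), and Aplnr, Ccl2, Cry2, Il1b, S100a9, Timp1 and Ttn (2 to 8 arrays each).

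Of 23 immediate early genes 19 rose and 4 did not pass (median 1.62; 22 higher adjusted over the list alone, adjusted p = 3.01e-22, and adjusted p = 0.159 with an estimated correlation). Btg2 stood at log2 2.57 and Maff at log2 2.42. Glucocorticoid-responsive genes gave 14 of 19 higher and 5 not passing (median 1.23; 16 higher adjusted over the list alone, adjusted p = 9.97e-14, and adjusted p = 0.195 with an estimated correlation). The stress kinase genes Map3k6 (log2 1.81) and Sgk1 (log2 1.32) were among them. Neutrophil markers rose in 9 of 10 (median 1.66; 10 higher adjusted over the list alone, adjusted p = 1.09e-07, and adjusted p = 0.195 with an estimated correlation). S100a8 was 3.73-fold higher (log2 1.90, SE 0.39). In the cytokine list 10 rose, 2 fell and 8 did not pass (median 0.74; 11 higher and 3 lower adjusted over the list alone, adjusted p = 0.000479, and adjusted p = 0.315 with an estimated correlation). Cxcl1 was 7.83-fold higher (log2 2.97, SE 0.53). Wound matrix genes gave 12 of 21 higher (median 0.67; 13 adjusted over the list alone, adjusted p = 8.92e-09, and adjusted p = 0.159 with an estimated correlation). Fetal and stress genes gave 8 of 14 higher (median 0.83; 9 adjusted over the list alone, adjusted p = 1.36e-06, and adjusted p = 0.195 with an estimated correlation). Hypoxia genes gave 6 of 23 higher (median 0.30, and 0.19 without wake sham replicate 2; 9 adjusted over the list alone, adjusted p = 0.000202, and adjusted p = 0.195 with an estimated correlation). Heat shock genes gave 9 of 25 higher (median 0.31; 10 higher and 2 lower adjusted over the list alone, adjusted p = 0.000370, and adjusted p = 0.195 with an estimated correlation).

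Fibroblast and collagen genes gave 0 higher, 6 lower and 15 not passing (median -0.33; 7 lower adjusted over the list alone, adjusted p = 0.00527, and adjusted p = 0.543 with an estimated correlation). Col1a1 stood at log2 -0.997 (SE 0.21), the matrix gene Fbln1 at log2 -0.91 (SE 0.11) and the fibroblast transcription factor gene Tcf21 at log2 -0.66. Atrial markers gave 3 lower and 4 not passing (median -0.94; 4 lower adjusted over the list alone, adjusted p = 0.0115, and adjusted p = 0.220 with an estimated correlation). Endothelial markers gave 7 higher and 3 lower of 21 (median 0.22; 8 higher and 7 lower adjusted over the list alone, adjusted p = 0.0181, and adjusted p = 0.439 with an estimated correlation). The transcription factor gene Sox17 (log2 1.91) and Rgcc (log2 1.93, SE 0.27) rose. Per, Rev-erb and PAR bZIP clock genes gave 3 higher and 8 not passing (median 0.37; 4 higher adjusted over the list alone, adjusted p = 0.00802, and adjusted p = 0.195 with an estimated correlation). They were Bhlhe40 (log2 1.44), Cry2 (log2 0.58) and Per1 (log2 0.95, SE 0.15). Leukocyte adhesion genes gave 6 higher of 14 (median 0.17; 6 adjusted over the list alone, adjusted p = 0.0115, and adjusted p = 0.226 with an estimated correlation). Pattern recognition genes gave 6 higher of 14 (median 0.31; 6 higher and 1 lower adjusted over the list alone, adjusted p = 0.0190, and adjusted p = 0.195 with an estimated correlation). Cardiomyocyte contractile genes gave 2 higher of 26 (median 0.13; 1 higher adjusted over the list alone, adjusted p = 0.00211, and adjusted p = 0.543 with an estimated correlation). Without wake MI replicate 3 the calls of the Per, pattern recognition and endothelial lists ended (adjusted p = 0.0609, 0.0609 and 0.221), and without wake sham replicate 3 that of the fibroblast list (median -0.18, adjusted p = 0.0720). The Per median was 0.20 and the adhesion median 0.07 without wake sham replicate 2, the adhesion median 0.34 and the atrial median -0.60 without wake sham replicate 3, and the endothelial median 0.34 and the contractile median 0.08 without wake MI replicate 1. With the beta-actin covariate the Per, pattern recognition, adhesion and endothelial calls ended (adjusted p = 0.0660, 0.139, 0.128 and 0.475). The cytokine, hypoxia, heat shock and contractile calls held with it, at smaller medians of 0.46, 0.18, 0.18 and 0.08. Nppb did not pass in wake hearts (log2 1.37, SE 0.65, adjusted p = 0.156), nor did Nppa (log2 -0.94), Per2 (log2 0.41) or Dbp (log2 0.37).

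In sleep hearts, MI was again compared with sham, 3 arrays each. The largest rises were those of Hspa1b and Hspa1a, followed by Atf3, Fos, Nppb and Ccn1. Hspa1b was 49.1-fold higher (log2 5.62, SE 0.51, adjusted p = 4.16e-05) at a signal of 2932 ± 666 against 43.8 ± 12.1 (SD, n = 3 each). Atf3 was 13.6-fold higher (log2 3.77, SE 0.28) at 696 ± 185 against 36.0 ± 10.5 (SD, n = 3 each). Hspa1a rose 18.9-fold, Fos 13.3-fold (log2 3.73, SE 0.40) and Ccn1 11.5-fold. Nppb, the stretch-responsive natriuretic peptide gene, was 12.6-fold higher (log2 3.66, SE 0.65, adjusted p = 0.00956) at 5858 ± 549 against 744 ± 897 (SD, n = 3 each). Il6 rose 6.29-fold (log2 2.65, SE 0.51, adjusted p = 0.0155), from 57.3 ± 48.7 in sleep sham hearts, and Ptx3 6.53-fold (log2 2.71, SE 0.65, adjusted p = 0.0416). Rsrp1 (log2 -1.51), the clock gene Per3 (log2 -1.16, SE 0.24, adjusted p = 0.0197), the natriuretic peptide receptor gene Npr3 (log2 -1.15), Hpgd (log2 -1.12) and the sulphur amino acid enzyme gene Cth (log2 -1.07) fell. No probe set of Npr3 passed when all its 3 were tested one by one.

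In limma 215 genes differed, 136 higher and 79 lower, and 83 of them by at least 2-fold. In all 215 the groups did not overlap, as in 23.5% of all genes tested against 10% by chance. Of the 38 called genes named by the fixed rule, 20 lost the call when 1 array was left out, among them Il6, Ptx3, Rsrp1, Per3, Npr3, Cth, Hlf, Tef, Hdc, Il1r2, Ccl2, Selp, Thbs1 and Adm. Another 17, among them Hspa1b, Atf3, Fos, Ccn1, Hbegf, Hpgd and Xirp1, kept it in each alternative and with each array left out. Nppb kept it with each array left out but lost it in some other alternative. The count was 62, 125 and 108 without sleep MI replicates 1, 2 and 3, and 95 and 83 without sleep sham replicates 1 and 3.

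Immediate early genes gave 14 of 23 higher and 9 not passing (median 1.29; 19 higher adjusted over the list alone, adjusted p = 6.86e-28). Wound matrix genes gave 8 of 21 higher and 13 not passing (median 0.71; 11 higher adjusted over the list alone, adjusted p = 3.79e-15). Fetal and stress genes gave 8 of 14 higher and 6 not passing (median 1.19; 10 higher and 1 lower adjusted over the list alone, adjusted p = 2.58e-14). These 3 lists passed with an estimated correlation too (adjusted p = 0.0415 each). Among their members Btg2 stood at log2 1.74, Adamts1 at log2 2.16, the growth factor Hbegf at 7.01-fold (log2 2.81) and Tnfrsf12a, a receptor of tissue repair, at log2 1.88. Hypoxia genes gave 4 of 23 higher (median 0.19; 7 adjusted over the list alone, adjusted p = 1.26e-07, and adjusted p = 0.111 with an estimated correlation). Adm, a vasodilator peptide gene, stood at log2 0.94. Neutrophil markers gave 2 of 10 higher (median 0.85; 5 adjusted over the list alone, adjusted p = 2.56e-07, and adjusted p = 0.179 with an estimated correlation), Hdc (log2 1.27) and Il1r2 (log2 1.47). S100a8 (log2 1.26) and S100a9 (log2 1.54) did not pass. The cytokine list gave 3 of 20 higher, Il6, Cxcl2 (log2 1.91) and Ccl2 (log2 1.44) (median 0.41; 6 adjusted over the list alone, adjusted p = 2.56e-07, and adjusted p = 0.179 with an estimated correlation). Cxcl1 did not pass (log2 2.02, SE 0.53, adjusted p = 0.0601). Heat shock genes gave 6 of 25 higher (median 0.10; 7 higher and 2 lower adjusted over the list alone, adjusted p = 5.64e-05, and adjusted p = 0.176 with an estimated correlation). On sleep sham replicate 3 the mean log2 signal was 5.57 for neutrophil markers and 5.77 for cytokine genes, against 6.45 and 6.73 and against 6.52 and 6.69 on the other 2 sleep sham arrays. Without it the median MI effects of these lists were 0.56 and 0.22. The hypoxia and heat shock medians were 0.09 and 0.06 without sleep MI replicate 3.

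Per, Rev-erb and PAR bZIP clock genes gave 0 higher, 3 lower and 8 not passing (median -0.37; 1 higher and 4 lower adjusted over the list alone, adjusted p = 0.0224, and adjusted p = 0.237 with an estimated correlation). These were Per3, Hlf (log2 -0.82) and Tef (log2 -0.65). Glucocorticoid-responsive genes gave 0 higher, 1 lower and 18 not passing (median 0.30; 3 higher and 1 lower adjusted over the list alone, adjusted p = 0.0202, and adjusted p = 0.597 with an estimated correlation). Without sleep sham replicate 3 (mean log2 signal 9.09, against 9.56 and 9.95 on the other 2) the median was 0.09 and the call ended (adjusted p = 0.266). The call ended too without sleep MI replicate 2 (adjusted p = 0.0556), and the median was 0.50 without sleep sham replicate 2. Monocyte markers gave 1 of 14 higher (median 0.42; 3 adjusted over the list alone, adjusted p = 0.000962, and adjusted p = 0.295 with an estimated correlation). The secreted matrix gene Thbs1 stood at log2 2.03. Adhesion genes gave 1 of 14 higher, Selp at log2 1.29 (median 0.24; 1 adjusted over the list alone, adjusted p = 0.00129, and adjusted p = 0.176 with an estimated correlation). Antioxidant genes gave 2 of 16 higher, Srxn1 in 1 of 3 probe sets (log2 0.82) and Txnrd1 (log2 0.71) (median 0.02; 5 adjusted over the list alone, adjusted p = 0.0125, and adjusted p = 0.423 with an estimated correlation). In the pattern recognition list 0 of 14 genes passed (0 adjusted over the list alone; median 0.28; adjusted p = 0.0115, and adjusted p = 0.176 with an estimated correlation). In the cell cycle list 0 of 14 passed (1 higher adjusted over the list alone; median 0.18; adjusted p = 0.0285, and adjusted p = 0.423 with an estimated correlation). At the 60th percentile filter the cell cycle median turned to -0.02 (adjusted p = 0.959), and its call ended without sleep MI replicate 1 or 3 or sleep sham replicate 2 (adjusted p = 0.0672 to 0.140; median 0.11 without sleep MI replicate 3 and 0.33 without 2). The cell cycle call ended with the beta-actin covariate too (median 0.14, adjusted p = 0.0830). Without sleep sham replicate 3 the monocyte, adhesion and pattern recognition medians were 0.17, 0.09 and 0.16, and without sleep MI replicate 3 the monocyte median was 0.19. The Per call ended without sleep MI replicate 3 or sleep sham replicate 2 (adjusted p = 0.0784 and 0.0683) and the antioxidant call without sleep MI replicate 2 (adjusted p = 0.0947), its median running from 0.00 to 0.13 over left-out arrays. Ppargc1a rose (log2 1.06) in 3 of its 5 probe sets, and Timp1 (log2 0.97), Il1b (log2 0.82), Pdk4 (log2 0.41), Col1a1 (log2 0.05) and Nppa (log2 -0.57) did not pass.

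Whether MI changed the heart differently in the wake and the sleep period was asked by the difference of the MI effects, wake minus sleep. In no single gene did that difference pass. Mt2 was nearest among genes named by the fixed rule (log2 2.79, SE 0.45, adjusted p = 0.0946). Its signal was high in sleep sham hearts (4402 ± 2042) as in both MI groups (6792 ± 540 and 7372 ± 401) and stood at 547 ± 233 in wake sham hearts (SD, n = 3 each). Timp3, an inhibitor of matrix proteases chosen after its values were seen, had the smallest adjusted p of 0.0503 (log2 1.06, SE 0.15). By limma 0 genes differed after adjustment, and 852 had an unadjusted p under 0.05 where 405 would by chance. The differences of Myl7 (log2 -6.50, SE 1.48, adjusted p = 0.136), Nppb (log2 -2.29, SE 0.92, adjusted p = 0.407), Per1 (log2 1.004, adjusted p = 0.132) and Il6 (log2 1.30, adjusted p = 0.546) did not pass. The count of 0 became 23 without wake sham replicate 2, 1 without sleep sham replicate 1, 35 without sleep sham replicate 3 and 39 with array weights.

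Across lists, 8 of 30 passed camera for this difference and 0 with an estimated correlation. For all 19 glucocorticoid-responsive genes the difference, wake minus sleep, was positive (median 1.02; 11 adjusted over the list alone, adjusted p = 4.41e-15, and adjusted p = 0.293 with an estimated correlation). It was positive too for all 11 Per, Rev-erb and PAR bZIP clock genes, whose median MI effect was 0.37 in wake and -0.37 in sleep hearts (median difference 0.71; 6 adjusted over the list alone, adjusted p = 3.96e-08, and adjusted p = 0.0504 with an estimated correlation). The beta-actin ratio and the hybridisation control signals were lowest in the wake sham hearts that enter these values. In 20 of 21 fibroblast and collagen genes the difference was negative (median -0.53, and -0.33 without sleep MI replicate 1; 2 lower adjusted over the list alone, adjusted p = 1.24e-05, and adjusted p = 0.803 with an estimated correlation). Col1a1 at log2 -1.04 and Col3a1 at log2 -1.48 did not pass singly. Across 8101 genes the MI effects of wake and sleep hearts correlated at r = 0.64 (Spearman's rho 0.51, jackknife SE of r over arrays 0.15), genes not being independent replicates. Both comparisons called 118 genes higher and 45 lower, where independent lists would share 10.6 and 8.44, and 0 genes were called in opposite directions. Of the 1496 genes called in wake hearts 1333 had the same sign in sleep hearts, and of the 215 called in sleep hearts 206 had the same sign in wake hearts.

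**Figure D2:**
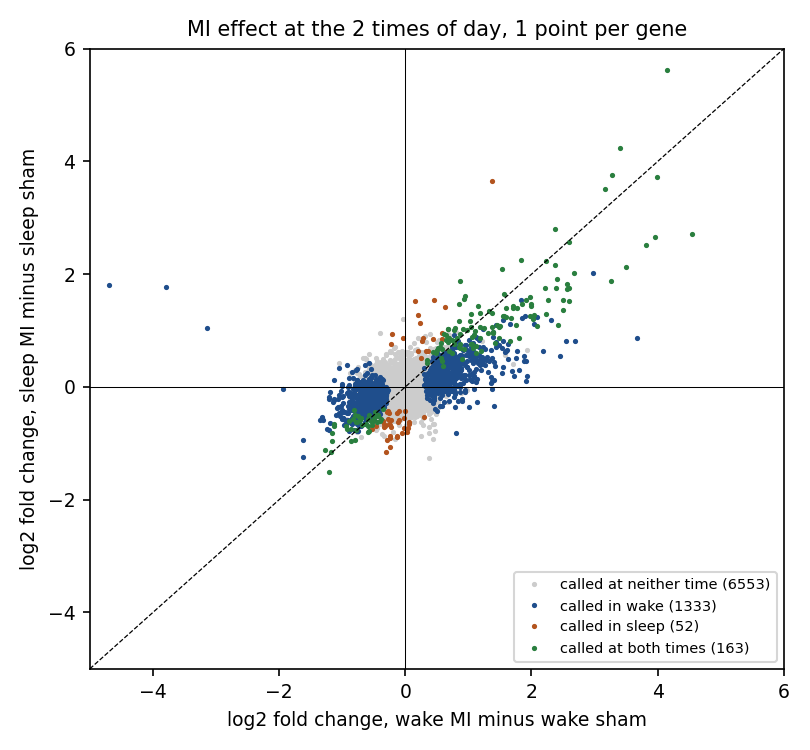
The MI effect of each of 8101 genes in wake hearts (x axis) and in sleep hearts (y axis), as log2 differences of log2(signal + 16), 3 arrays a group. Points are coloured by the comparison that called them: 163 genes in both, 1333 in wake hearts alone and 52 in sleep hearts alone. The difference between the effects passed for 0 genes.

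Wake sham and sleep sham hearts, 3 arrays each, showed how hearts of sham-operated mice differed between ZT23 and ZT11. Circadian clock genes differed strongly. Dbp, a clock-driven transcription factor gene, was 7.96-fold lower in wake sham hearts (log2 -2.99, SE 0.28, adjusted p = 9.24e-05), at 90.5 ± 26.9 against 820 ± 140 (SD, n = 3 each). Nr1d2, a repressor in the clock loop, was 3.51-fold lower (log2 -1.81, SE 0.18). Arntl, which codes for the core clock activator Bmal1, was 3.18-fold higher (log2 1.67, SE 0.21, adjusted p = 0.00120), at 115 ± 17.6 against 25.2 ± 6.09 (SD, n = 3 each). Nfil3, a repressor acting against Dbp, was 2.56-fold higher (log2 1.35, SE 0.15). Mt2 was 7.52-fold lower (log2 -2.91, SE 0.32), and Tcap, a sarcomere gene, 2.33-fold lower (log2 -1.22, SE 0.09, adjusted p = 1.03e-05). The insulin receptor substrate gene Irs1 (log2 1.14), the growth factor gene Vegfa (log2 1.13, 1 of 2 probe sets), Adam19 (log2 1.37) and Frmd5 (log2 1.16) were higher. The platelet chemokine gene Ppbp (log2 -1.92, SE 0.41), the mitochondrial carrier gene Slc25a33 (log2 -1.87), Slc10a6 (log2 -1.75) and the cytokine receptor gene Il17ra (log2 -1.61) were lower.

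In limma 123 genes differed, 34 higher and 89 lower in wake sham hearts, and 54 of them by at least 2-fold. The groups did not overlap in 122 of the 123, and in 20.1% of all genes tested against 10% by chance. The count ranged from 30 without wake sham replicate 1 to 226 without sleep sham replicate 3, and was 42, 51 and 35 without wake sham replicate 3 and sleep sham replicates 1 and 2. Of the 28 called genes named by the fixed rule, 15, among them Dbp, Nr1d2, Arntl, Nfil3, Per1, Per3, Tef, Mt2 and Tcap, kept the call in each alternative and with each array left out. The other 13, among them Nr1d1, Per2, Ppbp, Slc10a6, Adam19, Vegfa, Btg2, Zfp36, Bcl2l1 and Fas, lost it with 1 array left out.

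Per, Rev-erb and PAR bZIP clock genes gave 0 higher, 8 lower and 3 not passing (median -1.03; 11 lower adjusted over the list alone, adjusted p = 3.27e-20, and adjusted p = 0.00216 with an estimated correlation). Per3 stood at log2 -1.46 (SE 0.24), Tef at log2 -0.95, Per1 at log2 -1.06, Per2 at log2 -0.86 and Nr1d1 at log2 -1.34. The Bmal1 and Clock arm gave 2 of 6 higher and 4 not passing (median 0.58; 5 higher adjusted over the list alone, adjusted p = 7.64e-07, and adjusted p = 0.0322 with an estimated correlation). Glucocorticoid-responsive genes gave 0 higher, 8 lower and 11 not passing (median -0.999; 17 lower adjusted over the list alone, adjusted p = 1.49e-19, and adjusted p = 0.109 with an estimated correlation). Map3k6 was among them (log2 -1.51). Immediate early genes gave 3 lower and 20 not passing (median -0.48; 1 higher and 8 lower adjusted over the list alone, adjusted p = 5.27e-06, and adjusted p = 0.448 with an estimated correlation). The 3 were Btg2 (log2 -0.75), Maff (log2 -1.31) and Zfp36, which destabilises cytokine messages (log2 -1.31). Values of the next 2 lists and of the immediate early genes rest on 2 of the 3 sleep sham arrays. On sleep sham replicate 3 the mean log2 signal was 5.57 for neutrophil markers, 5.77 for cytokine genes and 6.72 for immediate early genes, within the wake sham ranges of 5.15 to 5.82, 5.75 to 6.10 and 6.63 to 6.77. None of 10 neutrophil markers passed singly (3 lower adjusted over the list alone; median -0.76; adjusted p = 2.04e-05, and adjusted p = 0.448 with an estimated correlation). Nor did any of 20 cytokine genes (2 higher and 8 lower adjusted over the list alone; median -0.36; adjusted p = 0.00264, and adjusted p = 0.552 with an estimated correlation). Il6 stood at log2 -1.66 and Cxcl1 at log2 -1.37. Without sleep sham replicate 2 the immediate early, neutrophil and cytokine medians were -0.24, -0.45 and -0.23, the cytokine call ending (adjusted p = 0.101) as it did without wake sham replicate 2 (adjusted p = 0.104). Without sleep sham replicate 3 the immediate early and cytokine medians were -0.74 and -0.64, and without wake sham replicate 1 the neutrophil median was -0.46.

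Cell death genes gave 2 lower of 16, Bcl2l1 (log2 -1.17, 1 of 2 probe sets) and the death receptor gene Fas (log2 -1.01) (median -0.07; 3 lower adjusted over the list alone, adjusted p = 0.0304, and adjusted p = 0.426 with an estimated correlation). Contractile genes gave 1 lower of 26, Tcap (median -0.07; 1 lower adjusted over the list alone, adjusted p = 0.0369, and adjusted p = 0.705 with an estimated correlation). No member passed singly in the interferon-stimulated list (median -0.21; 0 adjusted over the list alone, adjusted p = 0.0298, and adjusted p = 0.705 with an estimated correlation) or the wound matrix list (median -0.20; 2 lower adjusted over the list alone, adjusted p = 0.0362, and adjusted p = 0.561 with an estimated correlation). The same held for the pattern recognition list (median -0.11; 1 lower adjusted over the list alone, adjusted p = 0.0459, and adjusted p = 0.448 with an estimated correlation) and the atrial list (median 0.34; 0 adjusted over the list alone, adjusted p = 0.0369, and adjusted p = 0.448 with an estimated correlation). On sleep sham replicate 3 the mean log2 signals of the interferon-stimulated (6.42), wound matrix (5.96), pattern recognition (6.54) and atrial lists (7.57) lay within the wake sham ranges of 6.38 to 6.61, 5.91 to 6.18, 6.40 to 6.54 and 6.94 to 9.30. Each of the 6 list calls of this paragraph ended with some array left out. The interferon call ended without sleep sham replicate 2 (median -0.09, adjusted p = 0.534) or wake sham replicate 2 (adjusted p = 0.169), and the cell death call without wake sham replicate 3 (median -0.03, adjusted p = 0.0560) or sleep sham replicate 1 (adjusted p = 0.0678). The wound matrix call ended without wake sham replicate 1 or 2 or sleep sham replicate 1 or 2 (adjusted p = 0.0678 to 0.232; median -0.31 without wake sham replicate 3). That of the atrial list ended without wake sham replicate 3 (adjusted p = 0.216), wake MI replicate 1 or 3 or sleep sham replicate 1 or 2. That of the pattern recognition list ended without wake MI replicate 1, 2 or 3, wake sham replicate 1 or 2, sleep MI replicate 3 or sleep sham replicate 1 or 2 (adjusted p = 0.0512 to 0.154; median -0.18 without sleep sham replicate 2). The contractile call ended without wake MI replicate 3, wake sham replicate 2 or 3 or sleep sham replicate 1 or 3 (adjusted p = 0.0569 to 0.470), with medians from -0.22 without sleep sham replicate 2 to 0.00 without sleep sham replicate 3. Myl7 stood at log2 2.74 (SE 1.05, adjusted p = 0.252), Nppb at log2 1.95 (adjusted p = 0.181), Myh7, a myosin heavy chain, at log2 -2.002 (adjusted p = 0.0728) and Pdk4 at log2 -0.74 (adjusted p = 0.0618), none of which passed.

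**Figure D3:**
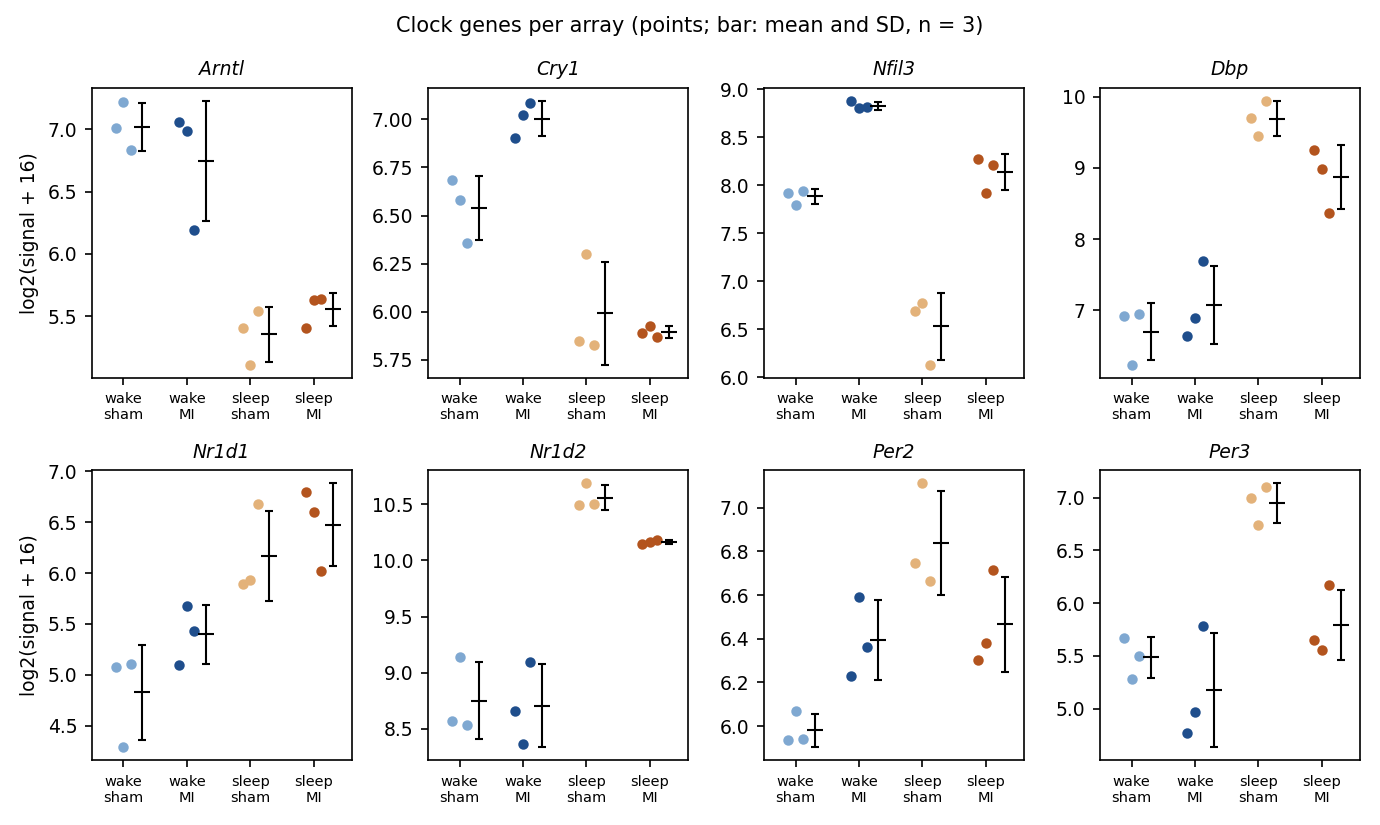
Signals of 8 circadian clock genes on each of the 12 arrays, as log2(signal + 16), by group (points are arrays, bars mean and SD, n = 3). Dbp was at 90.5 in wake sham and 820 in sleep sham hearts, and Arntl at 115 and 25.2.

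The last comparison set the MI hearts of the 2 times of day against each other, 3 arrays each. The 6 genes that differed included core clock genes. Cry1, a repressor in the clock loop, was 2.16-fold higher in wake MI hearts (log2 1.11, SE 0.14, adjusted p = 0.00702), at 113 ± 7.98 against 43.6 ± 1.21 (SD, n = 3 each). Nr1d2 was 2.75-fold lower (log2 -1.46, SE 0.18, adjusted p = 0.00702), Dbp 3.48-fold lower (log2 -1.80, SE 0.28, adjusted p = 0.0274) and Tcap 1.51-fold lower (log2 -0.60, SE 0.09, adjusted p = 0.0212). Gsta3, a glutathione transferase gene (log2 0.78, SE 0.12, adjusted p = 0.0304), and Bmi1, a chromatin repressor gene (log2 0.62, SE 0.10, adjusted p = 0.0470), were higher. Gsta3 passed in 1 of its 2 probe sets and Bmi1 in neither when probe sets were tested one by one.

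By limma 6 genes differed, 3 higher and 3 lower, and 540 had an unadjusted p under 0.05 where 405 would by chance. In all 6 the groups did not overlap, as in 10.9% of all genes tested against 10% by chance. Each of the 6 lost its call with some array left out. The count was 0 without sleep MI replicate 1, 1 without wake MI replicate 2, 2 without wake MI replicate 1, wake sham replicate 1 or sleep MI replicate 2, and 3 without sleep MI replicate 3 or sleep sham replicate 1.

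The Bmal1 and Clock arm gave 1 higher, Cry1, and 5 not passing (median 0.63; 4 higher adjusted over the list alone, adjusted p = 8.15e-08, and adjusted p = 0.0355 with an estimated correlation). Arntl stood at log2 1.19 (SE 0.21, adjusted p = 0.0560) and Nfil3 at log2 0.69 (adjusted p = 0.321). Per, Rev-erb and PAR bZIP genes gave 2 lower, Dbp and Nr1d2, and 9 not passing (median -0.24; 3 lower adjusted over the list alone, adjusted p = 4.03e-06, and adjusted p = 0.0642 with an estimated correlation). Per2 stood at log2 -0.07 and Per3 at log2 -0.62. Of 21 fibroblast and collagen genes none passed singly (median -0.34; 2 lower adjusted over the list alone, adjusted p = 8.15e-08, and adjusted p = 0.578 with an estimated correlation). Col1a1 stood at log2 -0.82 and Col3a1 at log2 -1.16. No member passed singly in the monocyte list (median -0.32; 0 adjusted over the list alone, adjusted p = 0.000377, and adjusted p = 0.578 with an estimated correlation) or the complement and coagulation list (median -0.21; 0 adjusted over the list alone, adjusted p = 0.000384, and adjusted p = 0.142 with an estimated correlation). Nor did one in the cytokine list (median -0.28; 0 adjusted over the list alone, adjusted p = 0.000556, and adjusted p = 0.616 with an estimated correlation) or the antioxidant list (median -0.17; 0 adjusted over the list alone, adjusted p = 0.0360, and adjusted p = 0.706 with an estimated correlation). The antioxidant call ended without wake MI replicate 3, the array of highest beta-actin ratio (median -0.05, adjusted p = 0.600), and without sleep MI replicate 2 or 3 (adjusted p = 0.202 and 0.0657). It ended with the beta-actin covariate as well (median -0.14, adjusted p = 0.0781). The Per median was -0.38 without wake MI replicate 3, and the fibroblast median -0.22 without wake MI replicate 2 and -0.20 without sleep MI replicate 1. Il6 (log2 -0.36), Cxcl1 (log2 -0.42), S100a8 (log2 -0.35), Nppb (log2 -0.34) and Timp1 (log2 -0.24) did not pass. Across 8101 genes the time differences of sham and of MI hearts correlated at r = 0.03 (rho -0.00, jackknife SE of r 0.13). Both comparisons called Dbp, Nr1d2 and Tcap lower, where independent lists would share 0.033 genes, and 80 of the 123 genes called between shams had the same sign between MI hearts.

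**Figure D4:**
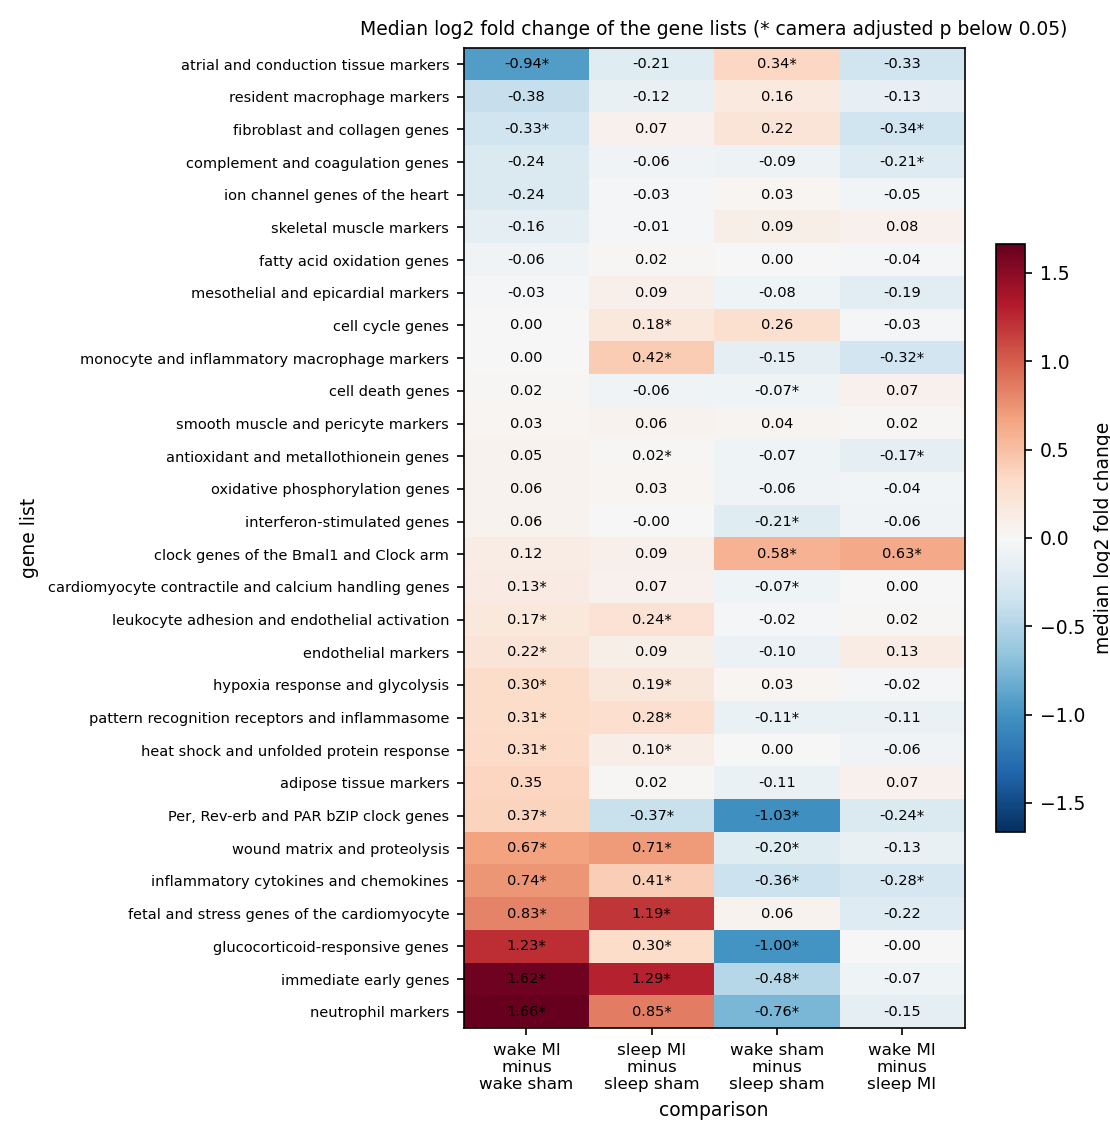
Median log2 difference of the members of each of 30 gene lists in 4 comparisons, by colour, with an asterisk where camera gave an adjusted p under 0.05. Immediate early genes stood at 1.62 in wake and 1.29 in sleep hearts after MI, and Per, Rev-erb and PAR bZIP clock genes at -1.03 between wake and sleep sham hearts.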

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

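Tests of the atrial genes, of the glucocorticoid-responsive genes and with the beta-actin covariate were chosen only after the result was seen, while the limits for the gene counts were set after the counts but before the values tested, as were those for the splits. In the covariate test and the atrial correlation test the value passed its limit against the explanation, and the reading was changed to open after the values were seen, because the first varied across the limit with single arrays left out and in the second the genes went both ways.

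The MI effect differed between wake and sleep hearts by camera in 8 of 30 lists, with 0 genes called singly (limma; 852 at an unadjusted p under 0.05) and 0 lists with an estimated correlation. The glucocorticoid-responsive genes had a median difference of 1.02 (adjusted p = 4.41e-15, and adjusted p = 0.293 with an estimated correlation). Per, Rev-erb and PAR bZIP clock genes stood at 0.711 (adjusted p = 3.96e-08, and adjusted p = 0.0504 with an estimated correlation). For fibroblast and collagen genes the median was -0.532, and -0.334 without sleep MI replicate 1 (adjusted p = 1.24e-05, and adjusted p = 0.803 with an estimated correlation). Immediate early genes stood at 0.461 (adjusted p = 0.00233, and adjusted p = 0.803 with an estimated correlation), the call ending without wake MI replicate 3 (0.224, adjusted p = 0.149) or sleep sham replicate 2 (0.338, adjusted p = 0.0734), against 0.762 without sleep sham replicate 3. The atrial and conduction markers gave -0.371 (adjusted p = 0.00856, and adjusted p = 0.446 with an estimated correlation), with -0.201 and -0.240 without wake MI replicate 2 and sleep sham replicate 2, and -0.706, -0.712 and -0.797 without wake sham replicates 1 and 2 and sleep sham replicate 3. Neutrophil markers gave 0.337 (adjusted p = 0.0391, and adjusted p = 0.814 with an estimated correlation), endothelial markers 0.139 (adjusted p = 0.0391, and adjusted p = 0.803 with an estimated correlation) and cell death genes 0.143 (adjusted p = 0.0391, and adjusted p = 0.446 with an estimated correlation). The neutrophil call ended without wake MI replicate 1 or 2, wake sham replicate 1 or 3, sleep MI replicate 1 or sleep sham replicate 1 or 2 (adjusted p = 0.0537 to 0.344; median 0.179 without sleep sham replicate 2 to 0.693 without 3), and the cell death call without wake MI replicate 3, wake sham replicate 1 or 3, sleep MI replicate 2 or sleep sham replicate 1 (adjusted p = 0.0530 to 0.118; median 0.105 without sleep MI replicate 2 to 0.289 without 3). The endothelial call ended without wake sham replicate 1, sleep MI replicate 2 or 3 or sleep sham replicate 1, and without wake MI replicate 3, where its median turned to -0.0203 (adjusted p = 0.633; 0.231 without wake MI replicate 1). Outside the named genes, 194 of 1042 probe sets without a single gene name differed between MI and sham over both times, 91 higher and 103 lower.

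More genes were called for MI against sham in wake hearts (1496) than in sleep hearts (215). Whether a single sleep sham array that stands apart gave this could not be decided by leaving each out. The sleep count was then 95, 227 and 83 and the wake count 1338, 1435 and 1511. A smaller group also lowers the sleep count, so it could hardly come near the wake count. RNA integrity stays open. The beta-actin ratio separated the wake groups (1.77 to 1.81 in sham, 2.17 to 3.31 in MI hearts), so as a covariate it cannot decide this. With it the counts were 274 and 172, just past the 1.5-fold limit set (ratio 0.369 to 6.50 with single arrays left out). The median absolute change in wake hearts was 0.213 without and 0.215 with it, the median standard error 1.36 times as large. Hybridisation control signals were lowest in wake sham hearts too (mean log2 9.41, against 9.67 to 9.81 elsewhere). Whether such a technical difference gave the larger wake count was not tested. A larger difference among sham than among MI hearts stays open, as 63.8% of the 1333 genes called in wake hearts alone differed more between shams, against 57.2% of all genes, with a range of 54.5% to 73.1% over left-out arrays. The time of surgery and of collection, which the design changes together, stays an open biological explanation, and the difference between the effects passed for 0 genes.

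Myl7, Sln and Myl4 were lower in wake MI than in wake sham hearts, the mean log2 signal of the 3 genes being 4.73, 4.67 and 4.74 on the 3 wake MI arrays and 6.47, 7.83 and 11.5 on the 3 wake sham arrays. Differing amounts of atrial tissue in the samples may be the source, and this could not be decided: the other atrial genes had a median correlation of -0.0779 with the mean of the 3 within groups but went both ways, with the abundant Nppa (mean signal 2053) at 0.929 and Tbx5, Stmn2 and Kcnj3 (48.1, 49.9 and 36.6) at -0.15, -0.00 and -0.51. A fall after MI at both times of day could not be excluded either. The mean difference in sleep hearts was 1.54 with a standard error of 1.27, against -3.88 (SE 1.27) in wake hearts. The difference between these effects, wake minus sleep, was -5.42 (SE 1.80). These standard errors are pooled over the 4 groups, although the arrays spread far more in wake sham than in wake MI hearts. Which part of each heart was sampled is not given in the sources used here.

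Glucocorticoid-responsive genes were higher in sleep sham than in wake sham hearts, the median for wake sham minus sleep sham being log2 -0.999 over 19 genes. A single sleep sham array was argued against, since that median stayed at -0.792 or further from 0 with each left out. Inflammation after sham surgery could not be excluded: the mean shift of the list was 2.45 times that of the cytokine list between shams and 1.10 times in the MI effect, but 1.79 to 3.68 times with single sham arrays left out, and 7 of the 20 genes of the list also stand in another list. A daily rhythm of glucocorticoid hormone is a candidate explanation that the design confounds with the time of surgery, and it was not tested.

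For MI against sham over both times, 1 of 100 splits of the 12 arrays reached the 1792 genes, and that split was the real grouping. The highest other gave 582, which argues against chance, 1 of 100 being the smallest share possible here. The 14 lists were reached by 17 splits (highest other 17). Chance cannot be excluded for them, but many other splits keep part of the real MI difference, so this count cannot decide it. Each count of splits in this paragraph includes the real grouping. For the difference of the effects 60 splits reached the 8 lists (highest other 18). These splits regroup wake and sleep arrays within MI and within sham hearts, so some of them hold part of the time difference. They cannot decide on chance for the 8 lists, which stays open. A count of 0 genes is reached by each of the 100 splits whatever the data, so the splits say nothing on it. The highest other split called 69 genes. Such a split can hold the time difference itself, which between sham hearts called 123 genes. What gave the 69 was not tested. In the comparisons of 3 against 3 arrays the 10 splits are too few for a share under 0.05: the real and the highest other counts were 1496 and 0 genes and 15 and 17 lists in wake hearts, 215 and 0 genes and 14 and 15 lists in sleep hearts, 6 and 1 genes and 7 and 11 lists between MI hearts, and 123 and 7 genes and 12 and 16 lists between sham hearts. Lists as many as the real ones came from 2, 4, 4 and 3 of these 10 splits.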

How the results depend on the processing

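The beta-actin covariate and leaving out the 2 arrays of highest ratio were chosen only after the result was seen. Of 191 calls of named genes, 109 were kept in each alternative and 82 lost in some, and none reversed; of 70 list calls, 6 were kept in each alternative. The cause was not tested except where an alternative tests fewer arrays or sets a stricter threshold. For MI against sham over both times 1792 genes became 672 with the covariate, 779 at an adjusted p below 0.01 and 125 at a log2 change of at least 1 (1314 to 1801 with 1 array left out). In wake hearts 1496 became 274, 564 and 228 in the same order (845 to 1511 with 1 array left out; 863 without wake sham replicate 1 and 845 without 3). In sleep hearts 215 became 140 with no level filter, 416 with array weights, 51 at an adjusted p below 0.01 and 83 at a log2 change of at least 1 (62 to 289 with 1 array left out; 62, 125 and 108 without sleep MI replicates 1, 2 and 3, and 95 and 83 without sleep sham replicates 1 and 3). Between MI hearts 6 became 2 with no level filter, 3 with the mean of probe sets, 3 with the compared groups alone, 2 at an adjusted p below 0.01 and 3 at a log2 change of at least 1 (0 to 7 with 1 array left out; 2 and 1 without wake MI replicates 1 and 2, 2 without wake sham replicate 1, 0, 2 and 3 without sleep MI replicates 1, 2 and 3, and 3 without sleep sham replicate 1). Between sham hearts 123 became 75 with no level filter, 74 with the mean of probe sets, 371 with array weights, 69 with the compared groups alone, 41 with the covariate, 33 at an adjusted p below 0.01 and 54 at a log2 change of at least 1 (30 to 226 with 1 array left out; 30 and 42 without wake sham replicates 1 and 3, and 51, 35 and 226 without sleep sham replicates 1, 2 and 3). For the difference of the effects 0 became 1 with a pseudocount of 1, 1 at the 60th percentile filter, 2 with quantile normalization, 1 with median centring, 1 with robust variances and 39 with array weights (0 to 35 with 1 array left out; 23 without wake sham replicate 2, and 1 and 35 without sleep sham replicates 1 and 3). Without the 2 arrays of highest ratio the counts were 1508, 1271, 165, 5, 167 and 0, the last 2 being those between shams and of the difference. Camera with an estimated correlation called 0 lists over both times, 0 in wake, 3 in sleep, 1 between MI hearts, 2 between shams and 0 for the difference, and fry 6 in sleep, 2 between MI hearts, 3 between shams and 1 for the difference. The 8 lists of the difference became 5 at the 60th percentile filter and 5 without the 2 arrays of highest ratio. With 1 array left out the lists called ranged from 13 to 15 over both times, 13 to 18 in wake, 12 to 19 in sleep, 6 to 13 between MI hearts (13 without wake MI replicate 2), 7 to 14 between shams (7 without sleep sham replicate 1) and 5 to 10 for the difference (5 without wake MI replicate 3 or sleep sham replicate 1). The median of the cell cycle list in sleep hearts reversed to -0.0172 (adjusted p = 0.959) at the 60th percentile filter, where adjusted p ran from 0.00130 to 0.959 over alternatives. The correlation of the MI effects ranged from 0.50 to 0.69 with 1 array left out, and that of the time differences from -0.02 to 0.11. In the 5 comparisons with called genes no scaling alternative moved the share called higher by over 10 percentage points. With the replicate number as a block the counts were 1684, 1415, 172, 3, 99 and 3 genes, but the numbers do not pair the samples: 3 of 12 same-numbered pairs correlated above 0.1 (range -0.18 to 0.25), and 4 pairs matched their own number best. Signal over background limits genes near the level filter, where MAS5 values have little order.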

Other observations

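All tests in this part were chosen only after the result was seen: 25 gene families were looked at in 6 comparisons, 150 tests, and in addition a set of 11 platelet genes in the same 6 comparisons. Of 74 genes of mitochondrial ribosomal proteins, which build the translation machinery inside mitochondria, 28 were lower and 0 higher after MI over both times (median log2 -0.19; camera adjusted p = 1.58e-05, and adjusted p = 0.742 with an estimated correlation). Mrpl49 (log2 -0.64, SE 0.10, adjusted p = 0.000663), Mrpl34 (log2 -0.59, SE 0.10, adjusted p = 0.000999) and Mrpl40 (log2 -0.38, SE 0.07, adjusted p = 0.00255) had the smallest p, with 6 arrays a side. In wake hearts 22 were lower and 1 higher (median -0.27, adjusted p = 2.02e-06, and adjusted p = 0.904 with an estimated correlation), and in sleep hearts 1 was lower (median -0.13, adjusted p = 0.0355, and adjusted p = 0.810 with an estimated correlation). The sleep call ended without sleep sham replicate 3 (median -0.07, adjusted p = 0.643) or sleep MI replicate 1 or 3 (adjusted p = 0.0641 and 0.0612), and the 1 gene lost its call without any of 9 arrays. The wake count of 22 was 9 without wake MI replicate 3, 5 and 6 without wake sham replicates 1 and 3 and 1 with the beta-actin ratio as a covariate. The difference between these effects had a median of -0.14 (adjusted p = 0.00108, and adjusted p = 0.921 with an estimated correlation) and called 0 genes. That median was -0.06 without wake MI replicate 3, the array with the highest beta-actin ratio, and -0.06 with the covariate, and both ended the call (adjusted p = 0.134 and 0.334). Wake against sleep, 63 of the 74 genes had a positive difference among sham hearts (median 0.16, adjusted p = 4.68e-05, and adjusted p = 0.911 with an estimated correlation), while the median among MI hearts was 0.00 (adjusted p = 0.985; -0.06 without wake MI replicate 1, adjusted p = 0.0471). The sham median was 0.10 without wake sham replicate 1 and 0.08 with the covariate. With the covariate the family passed in no comparison (adjusted p = 0.0598 over both times, 0.0623 in wake, 0.168 in sleep and 0.0943 between sham hearts). Of 47 genes of cytosolic ribosomal proteins 1 was higher and 2 lower over both times (median -0.04, adjusted p = 0.994). Among sham hearts they lay in the other direction from the mitochondrial set, 40 of 47 having a negative wake minus sleep difference (median -0.11, adjusted p = 0.000419, and adjusted p = 0.911 with an estimated correlation) with 0 called. That median was -0.16 without sleep sham replicate 2 and -0.06 without sleep sham replicate 3, where the call ended (adjusted p = 0.166). The count of 28 was 24 with quantile normalization, 20 with median centring and 2 with the beta-actin ratio as a covariate, where the median was -0.12. It was 16 without wake MI replicate 3, 11 and 12 without wake sham replicates 1 and 3, 15 and 16 without sleep MI replicates 1 and 3 and 12 without sleep sham replicate 3.

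Of 11 genes of blood platelets 4 were called lower in wake sham than in sleep sham hearts, the platelet chemokine gene Ppbp (log2 -1.92), Clec1b, a platelet lectin receptor (log2 -1.40), Plek (log2 -0.99) and Nrgn (log2 -0.88), with 3 arrays a group. The other 7 did not pass, among them the platelet factor gene Pf4 (log2 -0.22) and the integrin gene Itga2b (log2 -0.60). Between wake and sleep MI hearts none of the 11 passed (Ppbp log2 -0.17, Clec1b 0.01, Plek -0.28 and Nrgn 0.01). Tested as a set and not adjusted for the number of sets looked at, the 11 gave a camera p = 2.79e-09 between shams, and p = 0.0161 with an estimated correlation. It gave p = 0.00135 in wake hearts (p = 0.140 with an estimated correlation), p = 1.55e-05 for the difference of the MI effects (p = 0.0583), and p = 0.0691, 0.398 and 0.182 over both times, in sleep hearts and between MI hearts. The count of 4 between shams was 0 without wake sham replicate 1 or sleep sham replicate 1 or 2, 1 without wake sham replicate 2, 2 without sleep MI replicate 2 and 0 with the beta-actin covariate. In wake MI against wake sham hearts the same 4 were called higher (Ppbp log2 1.40, Clec1b 1.14, Plek 1.02 and Nrgn 0.55), and over both times Plek was (log2 0.66, adjusted p = 0.00560). That count of 4 was 1 without wake MI replicate 1 or wake sham replicate 1, 2 without wake MI replicate 2 or wake sham replicate 2 and 0 with the covariate, which ended the call of Plek over both times too. The comparison of wake MI and that of the shams share the wake sham arrays with opposite signs, so the calls are not separate observations. Across 8101 genes their changes correlated at r = -0.63, and at r = -0.49 on simulated arrays without any change (covariance -0.0769 and -0.0157). In sleep hearts and for the difference of the MI effects, which uses the same arrays, none passed (Ppbp log2 -0.34 and 1.74).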
